A study of Homo sapiens with 24 samples.

How the data were processed

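RNA from U937 cells was sequenced in 24 libraries, 3 in each of 8 groups: DMSO, UNC0638 at 2 and 4 µM, a scrambled hairpin, G9a hairpins 2 and 3, and SUV39H1 hairpins 2 and 4. Groups and replicate numbers were taken from the labels. Per the labels, libraries were made with a TruSeq RNA v2 kit, which does not mark strand, so reads of overlapping or antisense genes cannot be told apart. The authors aligned reads with STAR and counted them with featureCounts on hg19, per the submitters' processing notes, and versions, settings and the treatment of reads that map to several places are not given in the sources used here. The deposited gene table held whole-number counts for 55773 gene names with their coordinates, and the deposited repeat table held whole-number counts for 992 repeat names. Of the gene names, 122 lay in more than 1 place. Its deposited other value, a summed length per name in bases, was used only to find genes without introns. Counts of near-identical copies, such as HLA paralogs and repeats of 1 family, are uncertain because reads may be shared. The 37 mitochondrial names held 0 counts in every library.

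Library sizes were the sums over all gene names before any filter, 31545854 to 53803704 per library. Genes were kept by filterByExpr of edgeR 4.0.16 (minimum count 10, minimum total count 15), which left 20147, and scaled with TMM. A quasi-likelihood model (glmQLFit and glmQLFTest, R 4.3.3) with 1 mean per group was fitted to all 24 libraries, and each comparison was a contrast of those means. The knockdowns were compared with scrambled as the mean of their hairpins and per hairpin, the inhibitor doses with DMSO, and contrasts were made between hairpins, doses, knockdowns and controls, and between the 4 µM and G9a responses. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. The common dispersion was 0.00215, a biological coefficient of variation of 4.63%. Repeats were fitted in the same way with library sizes and TMM factors of the gene table, so that a shift of all repeats would remain visible, and 928 names passed the filter. No technical batch was given in the labels.

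Gene lists were tested with camera (limma 3.58.1) with an inter-gene correlation of 0.01, 2-sided, and p-values of the 21 lists in the 4 main comparisons (84 tests) were Benjamini-Hochberg adjusted together. Lists in the other contrasts were adjusted as a separate family, and so were the 14 repeat lists. Estimated correlations and fry were alternatives. The lists were interferon-stimulated genes, interferons and nucleic acid sensors, MHC class I, MHC class II, inflammatory NF-kB genes, monocyte and macrophage markers, myeloid progenitor genes, erythroid genes, lymphoid markers, epithelial and fibroblast markers, cell cycle, p53 and arrest, apoptosis, the integrated and endoplasmic reticulum stress response, cholesterol synthesis, lysosome and autophagy, MYC and ribosome biogenesis, germline, H3K9 methylation machinery, replication-dependent histones and ZNF genes. Repeat lists were LTR12, HERVH, HERVK, HERVE, HERVW, MER41 and MER61, THE1 with MST and MLT, MLT2, young and older LINE-1, Alu, SVA, satellites and DNA transposons.

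Genes were named by a rule. It took the 4 methyltransferase genes in every group. For 4 µM UNC0638, the G9a mean and the SUV39H1 mean it took the 12 higher and 12 lower genes with the largest fold change among those called. These needed a mean of at least 2 CPM, all treated libraries on 1 side of all 3 controls, both hairpins called in the same direction and a symbol that was not clone-based. It also took the 4 members with the smallest p of each list with at least 3 called members, 6 higher and 4 lower repeats, and 4 higher and 4 lower genes of the contrasts between hairpins, doses and knockdowns. The separation of libraries was not applied to the difference between the inhibitor and G9a responses, where each has its own control. The groups, comparisons, tests, lists, this rule and the alternative settings were fixed before the data were examined. Counts of interferon genes, and genes so described in the text, were chosen after their values were seen.

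The fit was tested on simulated counts drawn from the real means and library sizes. Of 50 genes changed per fold among 20147, at 4 µM UNC0638 38.0% were called at 1.2-fold, 66.0% at 1.5-fold, 82.0% at 2-fold and 94.0% at 4-fold, and 5.77% of calls were false. For the G9a mean these shares were 50.0%, 62.0%, 90.0% and 96.0%, with 7.69% false. For the SUV39H1 mean they were 42.0%, 70.0%, 92.0% and 100.0%, with 4.55% false. Of 24 repeats changed per fold among 928, 70.8%, 87.5%, 91.7% and 100.0% were called at 4 µM, with 2.83% false, 83.3%, 91.7%, 100.0% and 100.0% for the G9a mean, with 2.70% false, and 79.2%, 91.7%, 100.0% and 100.0% for the SUV39H1 mean, with 5.17% false. None of 20 unchanged lists passed camera in any of these simulations at an unadjusted p under 0.05. The counts were drawn independently for each gene or repeat, so camera was not tested on lists whose members vary together.

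Alternatives were DESeq2 1.42.0, RLE scaling, no filter on low counts, a stricter filter (1 CPM in 3 libraries and a mean count of 10), the replicate number as a block, a fit of the compared libraries alone, each library left out in turn, and TMM on the repeats themselves. Alternatives chosen after seeing the data were the DMSO libraries as the control of the knockdowns and the inhibitor arm without the libraries numbered 1. All 24 within-group pairs of libraries differed by more than sampling noise in a chi-square test of their counts (2.30 to 27.8 per degree of freedom), so none was counted as a repeat deposit. The human annotation at hand was of another build (GENCODE v29, GRCh38) and was used for gene types by name only.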

Results

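RNA-seq counts were available for U937 cells, a human myelomonocytic line that grows in suspension and can be driven towards monocytes and macrophages. The series concerned the enzymes that methylate lysine 9 of histone H3 (H3K9), a mark of silent chromatin, and the interferon pathway. G9a, the product of EHMT2, and its partner GLP, the product of EHMT1, mainly make the dimethyl form, and SUV39H1 and its paralog SUV39H2 mainly make the trimethyl form. The 24 libraries fell into 8 groups of 3. Cells received DMSO or 2 or 4 µM UNC0638, an inhibitor of the catalytic activity of G9a and GLP. Other cells carried a scrambled hairpin, hairpin 2 or 3 against G9a, or hairpin 2 or 4 against SUV39H1. Per the labels the cells with UNC0638 were harvested after 3 days, and those with G9a or SUV39H1 hairpins, brought in by lentivirus, were selected for 3 days in puromycin. The labels give no harvest time for the DMSO cells and no selection for the scrambled cells. Each library held 31545854 to 53803704 counts on genes and 1837411 to 4163513 counts on repeat names. Levels are given as CPM, counts scaled to library size, ± SD with n = 3 libraries per group, and fold changes on the log2 scale ± SE of the fit. For the mean of a knockdown's hairpins, the SE and p-value come from the spread within each hairpin group. They leave out the difference between the hairpins. The labels do not say that replicates came from separate cultures, so no p-value reaches beyond these samples, whose spread may be technical. Tests of single genes and repeats measure that spread. Camera compares a list with the remaining genes or repeats, so its p-values also rest on the preset correlation between members. They can be far smaller than those with an estimated correlation, and are not a measure of the spread between libraries alone.

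The targeted transcripts were examined first. EHMT2 (chromosome 6, 31847536 to 31865464, minus strand, hg19) stood at 144 ± 8.52 CPM with the scrambled hairpin and at 73.7 ± 2.79 and 73.2 ± 3.69 CPM with G9a hairpins 2 and 3, or 51.3% and 50.9% of that control. The G9a hairpins together lowered it by a log2 change of -0.97 ± 0.05 (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p = 9.2e-14). SUV39H1 (chromosome X, 48553945 to 48567403, plus strand) fell from 58.2 ± 1.67 CPM to 18.6 ± 0.403 and 21.1 ± 1.84 CPM with SUV39H1 hairpins 2 and 4, or to 32.0% and 36.3%. Its log2 change was -1.55 ± 0.05 (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p = 7.3e-19). The SUV39H1 hairpins also lowered the paralog SUV39H2 (chromosome 10, 14920819 to 14946314, plus strand) by a log2 change of -0.92 ± 0.06, EHMT1 (chromosome 9, 140513444 to 140764468, plus strand) by -0.56 ± 0.04 and EHMT2 by -0.29 ± 0.06. With the G9a hairpins SUV39H2 changed by -0.21 ± 0.05, while EHMT1 (-0.07 ± 0.04) and SUV39H1 (-0.08 ± 0.05) did not pass. None of the 4 transcripts passed the test at 4 µM UNC0638 over all libraries, where EHMT2 stood at 132 ± 9.03 CPM against 146 ± 17.8 CPM in DMSO. Without DMSO replicate 1 all 4 passed, EHMT2 at -0.23, EHMT1 at -0.15, SUV39H1 at -0.20 and SUV39H2 at 0.22, and EHMT2 also passed with no low-count filter (-0.14) and, chosen after the data were seen, without the libraries numbered 1 (-0.19). SUV39H2 was 0.24 ± 0.06 higher in scrambled than in DMSO libraries. Without scrambled replicate 2 this call (0.16) and that of SUV39H2 with the G9a hairpins (-0.14) ended. With G9a hairpin 2 alone SUV39H2 did not pass (-0.15 ± 0.06), but passed with RLE scaling (-0.17), with DESeq2 (-0.17), in the compared libraries alone (-0.15) and without scrambled replicate 1 or 3 (-0.18 and -0.19). All 6 libraries labelled with G9a hairpins had less EHMT2, and all 6 labelled with SUV39H1 hairpins less SUV39H1, than every other library.

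**Figure D1:**
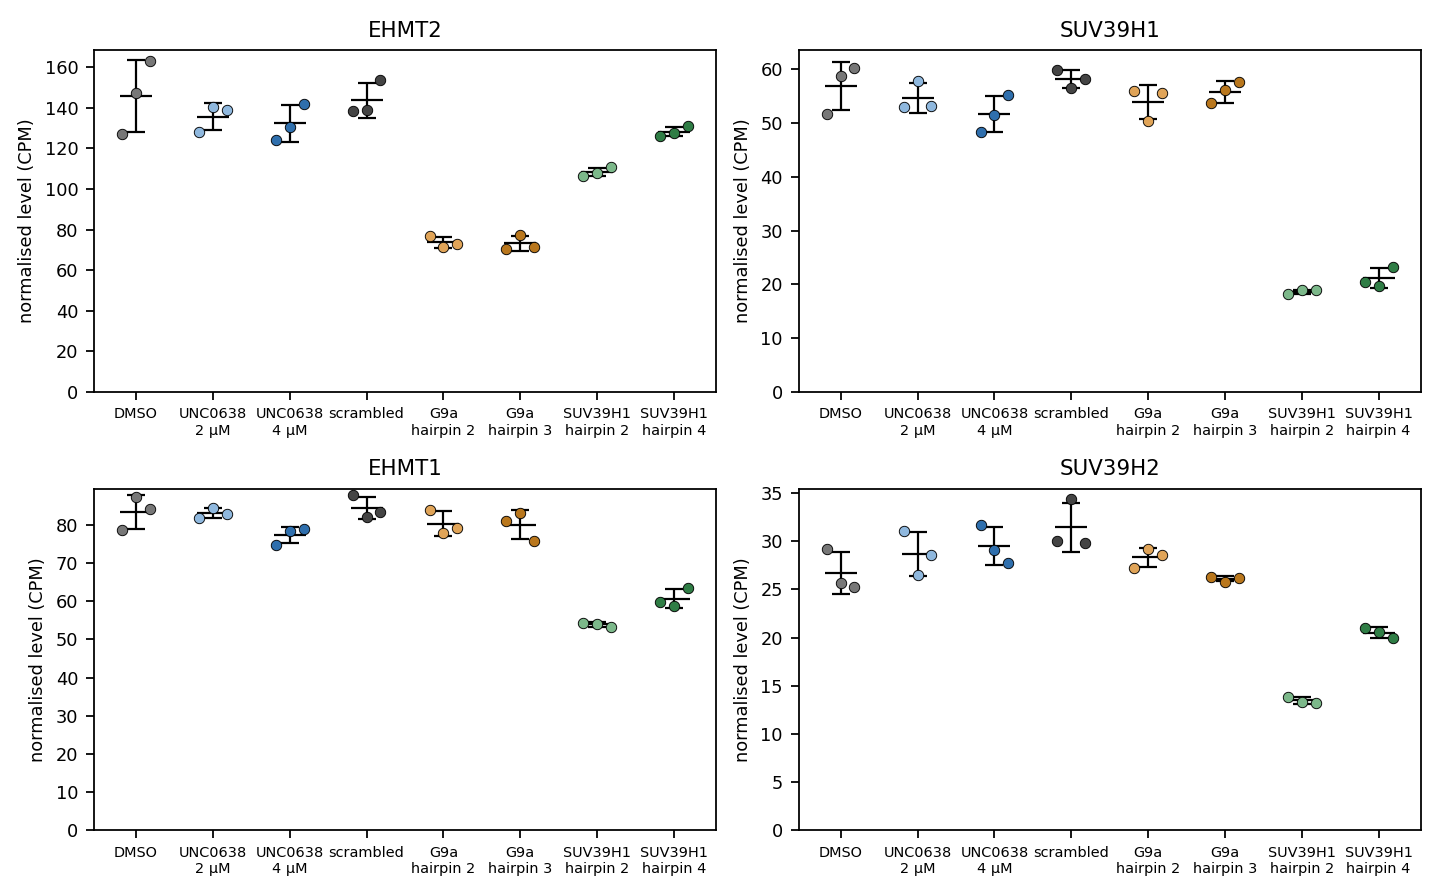
Normalised levels in CPM (y axis) of EHMT2, SUV39H1, EHMT1 and SUV39H2 in the 8 groups (x axis); points are the 3 libraries of a group and bars their mean ± SD. EHMT2 stands at 73.7 and 73.2 CPM in the G9a hairpin groups against 144 in scrambled, and SUV39H1 at 18.6 and 21.1 CPM in the SUV39H1 hairpin groups against 58.2.

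The first comparison asked which genes respond to inhibition of G9a and GLP. At 4 µM UNC0638 the interferon-stimulated genes, which cells switch on when they sense interferon, rose broadly. Of 73 measured members 64 rose, 1 fell and 8 did not pass, with a median log2 change of 0.97. SIGLEC1, a sialic acid-binding receptor of macrophages (chromosome 20, 3667617 to 3687775, minus strand), rose from 6.55 ± 1.2 to 55.6 ± 1.8 CPM, a log2 change of 3.08 ± 0.08. OAS1, which makes the 2'-5' oligoadenylates that activate RNase L (chromosome 12, 113344582 to 113369990, plus strand), rose from 16.4 ± 1.0 to 66.9 ± 2.1 CPM, and PARP9, a partner of the interferon response regulator DTX3L, from 33.3 ± 0.27 to 91.6 ± 2.4 CPM. IFI27 (chromosome 14, 94571182 to 94583033, plus strand) had the largest rise among the named genes, 4.10 ± 0.12, from 0.525 ± 0.043 to 8.98 ± 0.34 CPM. The antiviral enzyme OAS2 rose by 3.11 ± 0.16 and IFIT5, which binds viral RNA, by 2.13 ± 0.11. IRF1, a transcription factor of the pathway chosen after its values were seen, was the member that fell (-0.20 ± 0.06). Adjusted over the list alone, 66 members rose and 1 fell (camera, Benjamini-Hochberg adjusted p = 3.43e-252; adjusted p = 2.06e-14 with an estimated correlation).

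Several immune and myeloid lists moved with it at 4 µM. MHC class II genes, which present antigen from outside the cell, rose in 10 of 14 members (11 adjusted over the list alone), among them HLA-DRA at 66.2 ± 2.6 against 29.6 ± 0.74 CPM and HLA-DPB1 (2.11 ± 0.19, at no more than 1.65 CPM). The list had a median of 0.63 (camera, Benjamini-Hochberg adjusted p = 6.89e-17; adjusted p = 0.000309 with an estimated correlation). MHC class I genes rose in 14 of 22 members and fell in 1, the immunoproteasome subunit PSMB10 (chosen after its values were seen), with the same counts adjusted over the list alone and a median of 0.14 (camera, Benjamini-Hochberg adjusted p = 1.43e-08; adjusted p = 0.0141 with an estimated correlation). TAP1, the peptide transporter, rose by 0.48 ± 0.04 and HLA-B by 0.47 ± 0.04, with the caution that HLA genes are near-identical and can share reads. Monocyte and macrophage markers rose in 12 of 25 and fell in 2, or 12 and 3 adjusted over the list alone, with a median of 0.11 (camera, Benjamini-Hochberg adjusted p = 1.19e-07). The scavenger receptor CD36 rose from 54.4 ± 4.8 to 141 ± 5.3 CPM and MARCO, another scavenger receptor, from 14.9 ± 0.5 to 34.1 ± 1.2 CPM. Inflammatory NF-kB genes rose in 10 of 27 and fell in 1, or 11 and 2 adjusted over the list alone (median 0.07; camera, Benjamini-Hochberg adjusted p = 6.75e-06), including the chemokine CCL2 at 101 ± 0.98 against 50.6 ± 1.2 CPM. Primary granule and progenitor genes fell in 12 of 21 members and rose in none, over all genes and adjusted over the list alone (median -0.17; camera, Benjamini-Hochberg adjusted p = 1.14e-11). The granule proteases PRTN3, ELANE and CTSG fell by 1.17 ± 0.09, 0.78 ± 0.06 and 0.63 ± 0.04. These last 3 list calls held with an estimated correlation (adjusted p = 0.000113, 0.000642 and 0.000108).

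Genes of lysosomes rose in 12 of 32 members at 4 µM and fell in 2, or 14 and 4 adjusted over the list alone (median 0.09; camera, Benjamini-Hochberg adjusted p = 1.96e-07; adjusted p = 0.0494 with an estimated correlation). The cholesterol exporter of lysosomes NPC1 rose from 279 ± 13 to 629 ± 34 CPM and the glycoprotein GPNMB from 267 ± 5.4 to 541 ± 12 CPM. Sterol genes rose in 10 of 22 and fell in 2, or 11 and 2 adjusted over the list alone (median 0.11; camera, Benjamini-Hochberg adjusted p = 0.00533; adjusted p = 0.0135 with an estimated correlation). MYC target and ribosome biogenesis genes rose by little, in 10 of 32 members (13 adjusted over the list alone), with a median of 0.07 (camera, Benjamini-Hochberg adjusted p = 0.00569; adjusted p = 0.0462 with an estimated correlation). Zinc finger genes named ZNF, many of which recruit H3K9 methylation to repeats, fell in 125 of 369 members and rose in 11, or 133 and 13 adjusted over the list alone (median -0.13; camera, Benjamini-Hochberg adjusted p = 6.35e-11; adjusted p = 0.00158 with an estimated correlation). ZNF117 (chromosome 7, 64432154 to 64467062, minus strand) fell from 5.72 ± 0.37 to 1.23 ± 0.31 CPM and the endogenous retroviral envelope gene ERV3-1 (chromosome 7, 64451187 to 64467121, minus strand) from 4.72 ± 0.44 to 1.16 ± 0.11 CPM. Their intervals overlap on the same strand, so their reads may not be told apart. Apoptosis regulators rose in 7 of 25 members and fell in none, over all genes and adjusted over the list alone (median 0.09; camera, Benjamini-Hochberg adjusted p = 0.00529), with adjusted p = 0.0513 with an estimated correlation. H3K9 methylation machinery fell in 9 of 32 members and rose in 1, or 10 and 1 adjusted over the list alone (median -0.08; camera, Benjamini-Hochberg adjusted p = 0.0142), with adjusted p = 0.187 with an estimated correlation. Those that fell included the demethylases KDM3A (-0.32 ± 0.04) and KDM4B (-0.40 ± 0.05). The collagenase MMP1 (2.64 ± 0.07), the decoy receptor IL22RA2 (2.52 ± 0.08) and the tryptophan catabolism enzyme KYNU (2.12 ± 0.15) were among the largest rises outside the lists.

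The remaining lists did not pass camera at 4 µM over all libraries. Cell cycle genes passed without DMSO replicate 3 (median -0.06) and with no low-count filter (-0.05). Members rose and fell in 3 and 6 of 44 cell cycle genes, 2 and 3 of 23 p53 and arrest genes, 4 and 4 of 26 stress response genes, 1 and 3 of 7 lymphoid markers, 1 and 1 of 9 epithelial and fibroblast markers and 2 and 2 of 9 germline genes. Adjusted over the list alone, the counts were unchanged for cell cycle, lymphoid, epithelial and germline genes and became 3 and 5 for p53 genes and 6 and 6 for stress genes. In the stress and germline lists the medians (0.03 and 0.07) were positive while the means and tests pointed down, and in the histone list the median (0.04) and mean were positive while the test pointed down. Interferons and nucleic acid sensors rose in 5 of 21 members and fell in 1, over all genes and adjusted over the list alone, with a median of -0.0031 against a mean of 0.22 and a test pointing up (camera, Benjamini-Hochberg adjusted p = 0.0959). Without 4 µM replicate 1 this list passed and its median turned to 0.01. SAMHD1, which limits viral replication, was among the risers (0.82 ± 0.06). The interferon gene IFNB1 (chromosome 9, 21077104 to 21077943, minus strand) had 24 counts over the 3 libraries at 4 µM, 20 at 2 µM and 10 in DMSO, and did not pass. Of 4 erythroid genes and 16 histone genes none passed in edgeR's quasi-likelihood test, over all genes or adjusted over the list alone. Neither list passed camera with an estimated correlation (adjusted p = 0.729 and 0.922).

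Over all 20147 genes tested, 4012 (19.9%) differed at 4 µM, 2052 higher and 1960 lower, of which 315 and 60 differed at least 2-fold. The fit of the compared libraries alone called 1993.

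At 2 µM, of 73 interferon-stimulated genes 51 rose, 1 (IRF1) fell and 21 did not pass, with a median of 0.52. Adjusted over the list alone, 60 rose and 1 fell (camera, Benjamini-Hochberg adjusted p = 3.96e-140; adjusted p = 1.77e-13 with an estimated correlation). SIGLEC1 stood at 26.2 ± 0.67 CPM, OAS1 at 40.5 ± 1.3 CPM and OAS3 at 186 ± 4.1 against 93.4 ± 6.5 CPM in DMSO. MHC class II genes rose in 9 of 14, over all genes and adjusted over the list alone (median 0.55; camera, Benjamini-Hochberg adjusted p = 4.78e-20; adjusted p = 0.000113 with an estimated correlation), with HLA-DRA at 63.8 ± 3.3 CPM. MHC class I genes rose in 7 of 22, or 10 adjusted over the list alone (median 0.05; camera, Benjamini-Hochberg adjusted p = 0.00129), with adjusted p = 0.148 with an estimated correlation. Monocyte markers rose in 6 of 25 and fell in 3, or 9 and 4 adjusted over the list alone (median 0.08; camera, Benjamini-Hochberg adjusted p = 0.00165; adjusted p = 0.00598 with an estimated correlation). Progenitor genes fell in 9 of 21 and rose in none, or 10 and 1 adjusted over the list alone (median -0.14; camera, Benjamini-Hochberg adjusted p = 1.03e-07; adjusted p = 0.00068 with an estimated correlation), with PRTN3 at 210 ± 19 CPM. ZNF genes fell in 92 and rose in 4, or 114 and 9 adjusted over the list alone (median -0.10; camera, Benjamini-Hochberg adjusted p = 5.14e-16; adjusted p = 0.000295 with an estimated correlation). Ribosome biogenesis genes rose in 1 of 32, over all genes and adjusted over the list alone (median 0.06; camera, Benjamini-Hochberg adjusted p = 0.00645; adjusted p = 0.0484 with an estimated correlation). H3K9 machinery fell in 4 of 32, over all genes and adjusted over the list alone (median -0.05; camera, Benjamini-Hochberg adjusted p = 0.0196), with adjusted p = 0.2 with an estimated correlation. Without 2 µM replicate 1 this call ended (median -0.03). The other 13 lists did not pass camera, although some passed under other settings: with no low-count filter NF-kB genes (0.07) and apoptosis regulators (0.04), and with 1 library left out NF-kB genes without 2 µM replicate 1 or DMSO replicate 2 or 3 (medians 0.08, 0.06 and 0.07), lysosome genes without the same libraries (0.03, 0.02 and 0.03) and apoptosis regulators without DMSO replicate 1 (0.09). Members rose and fell in 3 and 0 of 21 sensors, 3 and 1 of 27 NF-kB genes, 0 and 1 of 4 erythroid genes, 1 and 2 of 7 lymphoid markers, 1 and 0 of 9 epithelial markers, 0 and 1 of 44 cell cycle genes, 2 and 1 of 23 p53 genes, 3 and 1 of 25 apoptosis regulators, 0 and 2 of 26 stress genes, 1 and 1 of 22 sterol genes, 4 and 1 of 32 lysosome genes, 0 and 2 of 9 germline genes and 0 and 0 of 16 histone genes. Adjusted over the list alone, the counts became 4 and 2 for NF-kB, 1 and 3 for lymphoid, 2 and 2 for p53 and 2 and 2 for sterol genes and were otherwise unchanged. The sensor and epithelial medians (-0.0081 and -0.05) lay below 0 while their tests pointed up, and the p53 and stress medians (0.01 and 0.0038) above 0 while theirs pointed down. In all, 1444 genes differed at 2 µM, 771 higher and 673 lower, and 180 and 24 at least 2-fold. Without DMSO replicate 1 the count was 2197, and the fit of the compared libraries alone called 717.

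Between the doses, 55 of 73 interferon-stimulated genes were higher at 4 than at 2 µM and none lower, or 62 and 0 adjusted over the list alone, with a median of 0.44 (camera, Benjamini-Hochberg adjusted p = 9.72e-230; adjusted p = 1.53e-15 with an estimated correlation). OAS2 was higher by 1.48 ± 0.13, IFI27 by 1.44 ± 0.08 and TDO2, a tryptophan dioxygenase, by 1.31 ± 0.14. The hormone STC1 (-0.60 ± 0.11) and SPAG4 (-0.51 ± 0.09) were lower. Lysosome genes were higher in 5 of 32, or 10 adjusted over the list alone (median 0.10; camera, Benjamini-Hochberg adjusted p = 8.57e-14; adjusted p = 0.00739 with an estimated correlation), and progenitor genes lower in 4 of 21, or 5 adjusted over the list alone (median -0.10; camera, Benjamini-Hochberg adjusted p = 3.61e-09; adjusted p = 0.00026 with an estimated correlation). In all, 371 genes differed, 280 higher and 91 lower at 4 µM. The count was 243, 215 and 246 without 2 µM replicates 1, 2 and 3, 224 without 4 µM replicate 2 and 236 from the compared libraries alone. Fold changes at the doses correlated across genes, which are not independent replicates (Pearson r = 0.82, Spearman rho = 0.74), where unchanged groups simulated against the shared DMSO libraries gave r = 0.52. The covariance was 0.0950 against 0.0234 simulated. Both doses raised 714 genes, where independent lists would share 78.5, lowered 615, where they would share 65.5, and moved 0 genes in opposite directions by edgeR's quasi-likelihood test. The 3 DMSO libraries cannot be split into parts of at least 2 each, so part of the excess may come from the shared controls.

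**Figure D2:**
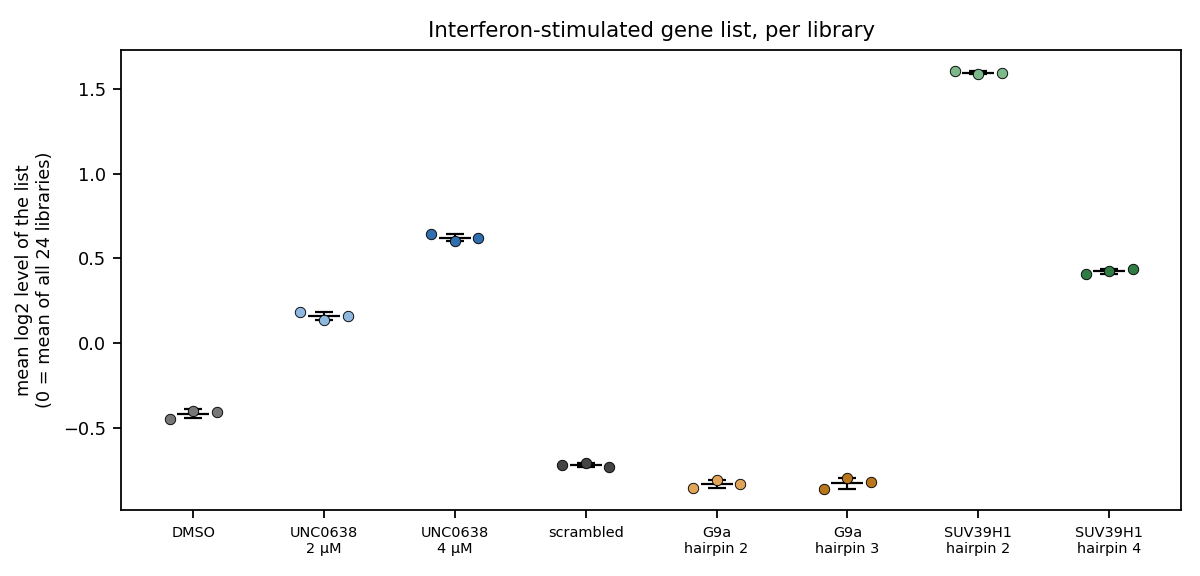
Mean log2 level of the 73 interferon-stimulated genes in each of the 24 libraries (y axis, 0 is the mean of all libraries) by group (x axis); points are libraries and bars mean ± SD of 3. The 4 µM libraries lie at 0.60 to 0.64, SUV39H1 hairpin 2 at 1.59 to 1.61, hairpin 4 at 0.41 to 0.44 and the G9a hairpins at -0.86 to -0.80, against -0.45 to -0.40 in DMSO and -0.73 to -0.71 in scrambled libraries.

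No rescue was analysed, so changes with the G9a hairpins cannot be assigned to less EHMT2 transcript alone. With EHMT1 not past the threshold and no protein measured here, these hairpins were compared with scrambled. They raised CHI3L1, a chitinase-like glycoprotein secreted by macrophages (chromosome 1, 203148059 to 203155877, minus strand), from 309 ± 9.2 CPM to 1665 ± 13 and 1840 ± 69 CPM with hairpins 2 and 3, a log2 change of 2.50 ± 0.04 (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p = 8.5e-25; all 6 libraries above the controls). KCNMB1, a potassium channel subunit (chromosome 5, 169801675 to 169816681, minus strand), rose from 5.98 ± 0.12 to 46.0 ± 1.3 and 49.5 ± 3.7 CPM, and the lipid droplet protein PLIN2 from 71.7 ± 0.59 to 220 ± 6.5 and 246 ± 16 CPM. RAD23B, a nucleotide excision repair factor (chromosome 9, 110045418 to 110094475, plus strand), fell from 295 ± 9.9 to 75.9 ± 0.3 and 74.2 ± 3.0 CPM. The dipeptidase DPEP1 fell by 2.55 ± 0.05, choline acetyltransferase CHAT by 2.33 ± 0.05, the semaphorin SEMA4C by 2.15 ± 0.05 and the immediate early factor EGR1 by 1.92 ± 0.07. HMOX1, which degrades haem, rose by 1.63 ± 0.06 against scrambled, from 8.81 ± 0.21 to 27.9 ± 2.5 and 26.6 ± 0.38 CPM, and lay below the DMSO libraries (105 ± 9.9 CPM), against which its change was -1.95.

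Interferon-stimulated genes moved both ways with the G9a hairpins: of 73 members 21 rose, 31 fell and 21 did not pass, over all genes and adjusted over the list alone. The median was -0.06 and the mean -0.21 (camera, Benjamini-Hochberg adjusted p = 0.377; adjusted p = 0.331 with an estimated correlation). Without G9a hairpin 3 replicate 2 or scrambled replicate 2 the median was -0.13 in each case. The ubiquitin ligase TRIM25 fell by 0.69 ± 0.03 and TRIM22, an antiviral protein, by 1.18 ± 0.07, while IRF1 rose by 0.57 ± 0.05. With fry, which asks whether the members move on balance one way, the fall passed (Benjamini-Hochberg adjusted p = 2.34e-06). Against DMSO libraries in place of scrambled 45 were lower and 7 higher (median -0.35). Scrambled libraries themselves lay below DMSO in this list (median -0.32), so the fall against DMSO includes the gap between the controls. Interferons and sensors rose in 9 of 21 members and fell in 3 (median 0.09; camera, Benjamini-Hochberg adjusted p = 0.144), with IFNB1 at 10 and 8 counts over 3 libraries each against 12 in scrambled. MHC class I genes rose in 9 of 22 and fell in 2 (median 0.13; camera, Benjamini-Hochberg adjusted p = 0.0759), and passed with no low-count filter (median 0.13). MHC class II genes fell in 7 of 14 and rose in 3 (median -0.14; camera, Benjamini-Hochberg adjusted p = 0.0373), with adjusted p = 0.255 with an estimated correlation. Without scrambled replicate 3 this call ended (median -0.10). HLA-DRA stood at 21.6 ± 1.3 and 24.9 ± 3.1 CPM against 42.3 ± 1.4 CPM. Counts of these 3 lists were unchanged adjusted over the list alone.

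Ribosome biogenesis and MYC target genes fell with the G9a hairpins in 28 of 32 members and rose in none, over all genes and adjusted over the list alone (median -0.27; camera, Benjamini-Hochberg adjusted p = 1.14e-11; adjusted p = 0.000113 with an estimated correlation). The nucleolar helicase DDX21 fell from 658 ± 30 to 323 ± 6.3 and 305 ± 11 CPM and NCL, or nucleolin, by 0.36 ± 0.03. Against the DMSO libraries this list had a median of 0.05 and NCL a change of 0.04, so their direction depended on which control was used. Stress response genes fell in 15 of 26 and rose in 5, or 17 and 5 adjusted over the list alone (median -0.20; camera, Benjamini-Hochberg adjusted p = 1.76e-07; adjusted p = 0.000159 with an estimated correlation), including the pseudokinase TRIB3 at 82.7 ± 2.7 and 82.6 ± 2.6 against 155 ± 6.5 CPM. Sterol genes fell in 12 of 22 and rose in 2, over all genes and adjusted over the list alone (median -0.14; camera, Benjamini-Hochberg adjusted p = 0.00369; adjusted p = 0.0105 with an estimated correlation), with INSIG1, which retains the sterol sensor, at -0.70 ± 0.04. Against DMSO the list median was 0.14 and INSIG1 changed by 0.04. NF-kB genes fell in 13 of 27 and rose in 6, or 13 and 7 adjusted over the list alone (median -0.10; camera, Benjamini-Hochberg adjusted p = 0.00814; adjusted p = 0.0171 with an estimated correlation), with CCL2 at 30.8 ± 1.2 and 31.3 ± 2.6 against 95.5 ± 3.1 CPM and TNF lower by 0.85 ± 0.07. Monocyte markers rose in 12 of 25 and fell in 3, over all genes and adjusted over the list alone (median 0.43; camera, Benjamini-Hochberg adjusted p = 0.0111; adjusted p = 0.0188 with an estimated correlation). Against DMSO this list did not pass, with 9 higher, 8 lower and a median of -0.04. Lysozyme, LYZ, rose from 474 ± 18 to 905 ± 34 and 922 ± 31 CPM, while CD36 fell by 0.96 ± 0.05 against scrambled and was 0.13 higher against DMSO.

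Lysosome genes rose in 20 of 32 members and fell in 3, over all genes and adjusted over the list alone (median 0.25; camera, Benjamini-Hochberg adjusted p = 0.00109), with adjusted p = 0.2 with an estimated correlation. The sterol carrier NPC2 rose by 0.54 ± 0.04, while GPNMB fell by 1.01 ± 0.03. Against DMSO the list did not pass camera (median 0.04, Benjamini-Hochberg adjusted p = 0.766). Lymphoid markers, a check for another cell type, fell in 4 of 7 members (median -0.26; camera, Benjamini-Hochberg adjusted p = 0.000541), with adjusted p = 0.098 with an estimated correlation. CD79A, a B cell receptor chain, fell from 18.1 ± 1.6 to 3.56 ± 0.18 and 4.08 ± 0.13 CPM. Histone genes fell in 4 of 16, or 3 adjusted over the list alone (median -0.52; camera, Benjamini-Hochberg adjusted p = 0.0856), with a median of -0.21 without scrambled replicate 2 and -0.08 against DMSO. Progenitor genes rose in 10 of 21 and fell in 5 (median 0.29; camera, Benjamini-Hochberg adjusted p = 0.0566), with ELANE at 807 ± 86 and 838 ± 29 against 465 ± 25 CPM and MYC at 210 ± 4.3 and 209 ± 6.0 against 283 ± 9.9 CPM. Against DMSO, MYC did not pass (-0.04). The progenitor list passed without G9a hairpin 2 replicate 3, G9a hairpin 3 replicate 1 or 3 or scrambled replicate 1 (medians 0.28, 0.31, 0.32 and 0.27), and histone genes without scrambled replicate 1 (-0.49). With no low-count filter both passed (0.31 and -0.52), as did ZNF genes (0.09) and H3K9 machinery (0.10), and against DMSO the progenitor list passed too (0.17). ZNF genes rose in 124 of 369 and fell in 59, or 124 and 58 adjusted over the list alone (median 0.08; camera, Benjamini-Hochberg adjusted p = 0.0912), and passed without scrambled replicate 2 (median 0.09). The 15 cell cycle genes that rose and 18 that fell of 44 included BUB1B (-0.81 ± 0.03), a spindle checkpoint kinase, and the transcription factor E2F1 (0.44 ± 0.04). Genes rose and fell in 8 and 8 of 23 p53 targets, 8 and 8 of 25 apoptosis regulators, 16 and 7 of 32 H3K9 machinery genes, 2 and 4 of 9 germline genes, 2 and 2 of 9 epithelial markers and 0 and 2 of 4 erythroid genes, and none of these lists passed camera. The arrest gene CDKN1A rose by 1.10 ± 0.05. Where not given, counts adjusted over the list alone were unchanged.

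In all, 10058 genes (49.9%) differed between the G9a hairpins and scrambled, 5038 higher and 5020 lower, of which 371 and 261 differed at least 2-fold. The G9a hairpins gave 8946 and 9004 calls separately. Between them 2 genes passed in edgeR's quasi-likelihood test, EGR1 (-0.65 ± 0.10, hairpin 2 minus hairpin 3) and the heat shock gene HSPA6 (0.49 ± 0.08), each with a Benjamini-Hochberg adjusted p = 0.0099. Without hairpin 2 replicate 1, 2 or 3, or hairpin 3 replicate 3, edgeR called 0, and without hairpin 3 replicate 1 it called 1. Over all libraries DESeq2 called 3, and 771 genes (3.83%) had an unadjusted p under 0.05 in edgeR. EHMT2 differed by 0.01 ± 0.07 between these hairpins. No list had a member past the threshold over all genes in edgeR's test. Camera still passed for small shifts, among them MHC class II genes (median -0.14, Benjamini-Hochberg adjusted p = 0.000271; adjusted p = 0.0522 with an estimated correlation) and ribosome genes (median 0.04, Benjamini-Hochberg adjusted p = 0.000669; adjusted p = 0.0158 with an estimated correlation).

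With the SUV39H1 hairpins the interferon-stimulated genes rose most broadly. Of 73 members 68 rose, 3 fell and 2 did not pass, over all genes and adjusted over the list alone, with a median of 1.67 (camera, Benjamini-Hochberg adjusted p = 1.55e-94; adjusted p = 4e-10 with an estimated correlation). SIGLEC1 rose from 7.02 ± 0.4 CPM in scrambled to 224 ± 6.8 and 85.0 ± 4.9 CPM with hairpins 2 and 4, a log2 change of 4.30 ± 0.07 (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p = 2.8e-25; all 6 libraries above the controls). IFI6, a mitochondrial survival protein (chromosome 1, 27992572 to 27998729, minus strand), rose from 36.6 ± 2.1 to 1234 ± 57 and 376 ± 15 CPM and OAS1 from 10.2 ± 0.28 to 161 ± 2.5 and 51.1 ± 1.5 CPM. PARP9 rose by 2.15 ± 0.04. The members that fell were PNPT1 (-0.48 ± 0.04), IFITM2 (-0.34 ± 0.09) and MX2 (-0.14 ± 0.03), of which IFITM2 and MX2 were chosen after their values were seen. IFI44L reached 8.84 ± 0.42 CPM with hairpin 2 and 0.351 ± 0.078 CPM with hairpin 4 from 0.0426 ± 0.04 CPM. Interferons and sensors rose in 16 of 21 members and fell in 2, or 17 and 2 adjusted over the list alone (median 0.35; camera, Benjamini-Hochberg adjusted p = 1.55e-05; adjusted p = 0.00136 with an estimated correlation). IFNB1 rose by 1.88 ± 0.38, from 12 counts over the 3 scrambled libraries to 80 and 29 with hairpins 2 and 4, and the DNA sensor AIM2 by 1.98 ± 0.11. IFNA1 (10 and 7 counts against 0) and IFNL1 (15 and 3 against 3) were too low to test, and IFNG had 0 counts in every group.

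MHC class I genes rose in 17 of 22 members and fell in 5 with the SUV39H1 hairpins (median 0.75; camera, Benjamini-Hochberg adjusted p = 6.14e-10; adjusted p = 0.0105 with an estimated correlation). HLA-B stood at 1390 ± 25 and 1023 ± 23 CPM against 483 ± 13 CPM, while the peptide-loading chaperone CALR, chosen after its values were seen, fell by 0.49 ± 0.05. MHC class II genes rose in 7 of 14 and fell in 2 (median 0.72; camera, Benjamini-Hochberg adjusted p = 0.00255), with adjusted p = 0.106 with an estimated correlation, and the thiol reductase IFI30 rose by 1.24 ± 0.05. Monocyte and macrophage markers rose in 21 of 25 and fell in 2 (median 1.30; camera, Benjamini-Hochberg adjusted p = 9.36e-14; adjusted p = 1.21e-05 with an estimated correlation). LYZ rose from 474 ± 18 to 2477 ± 31 and 1318 ± 19 CPM, and the integrins ITGAM by 2.03 ± 0.05, to 271 ± 12 and 154 ± 6.4 CPM, and ITGAX by 2.09 ± 0.07. The fungal glucan receptor CLEC7A (4.80 ± 0.17), the formyl peptide receptor FPR1 (3.33 ± 0.17) and the chemokine receptor CCR2 (3.26 ± 0.09) rose from under 2 CPM, while another myeloid lectin, CLEC5A, fell from 86.6 ± 3.1 to 9.47 ± 0.24 and 25.4 ± 1.3 CPM. NF-kB genes rose in 20 of 27 and fell in 4 (median 0.71; camera, Benjamini-Hochberg adjusted p = 5.14e-07; adjusted p = 0.000682 with an estimated correlation), with CCL2 at 258 ± 2.4 and 193 ± 8.8 CPM against 95.5 ± 3.1 CPM. Lysosome genes rose in 23 of 32 and fell in 2 (median 0.44; camera, Benjamini-Hochberg adjusted p = 9.14e-11; adjusted p = 0.0171 with an estimated correlation), with the sphingolipid activator precursor PSAP at 1219 ± 31 and 820 ± 24 against 467 ± 17 CPM. Counts in this paragraph were unchanged adjusted over the list alone.

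Ribosome biogenesis and MYC target genes fell in all 32 measured members with the SUV39H1 hairpins, over all genes and adjusted over the list alone (median -0.92; camera, Benjamini-Hochberg adjusted p = 2.26e-40; adjusted p = 3.45e-08 with an estimated correlation). NCL fell from 1687 ± 39 to 766 ± 19 and 769 ± 20 CPM, ODC1, the first enzyme of polyamine synthesis, by 1.14 ± 0.03 and MYC itself from 283 ± 9.9 to 86.4 ± 1.7 and 142 ± 2.2 CPM. Cell cycle genes fell in 24 of 44 and rose in 12, or 25 and 12 adjusted over the list alone (median -0.12; camera, Benjamini-Hochberg adjusted p = 0.00101; adjusted p = 0.0141 with an estimated correlation), with the replication factors GINS2 at -1.03 ± 0.03 and CDC6 at -0.91 ± 0.03. Targets of p53 and arrest genes rose in 15 of 23 and fell in 4 (median 0.40; camera, Benjamini-Hochberg adjusted p = 6.36e-05; adjusted p = 0.00437 with an estimated correlation), and the cyclin-dependent kinase inhibitor CDKN1A rose from 11.9 ± 0.39 to 83.7 ± 0.46 and 39.6 ± 1.8 CPM. Sterol genes fell in 14 of 22 and rose in 2 (median -0.28; camera, Benjamini-Hochberg adjusted p = 0.00129; adjusted p = 0.00579 with an estimated correlation), with INSIG1 lower by 1.06 ± 0.04. Against DMSO the sterol list did not pass, with 8 higher, 11 lower and a median of -0.10. The telomerase gene TERT fell by 2.36 ± 0.09 and the purine salvage enzyme PNP from 431 ± 14 to 87.7 ± 3.2 and 156 ± 2.7 CPM. HMOX1 rose by 3.23 ± 0.06 against scrambled, while its change against DMSO was -0.35.

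The other lists did not pass camera with the SUV39H1 hairpins. Members rose and fell in 10 and 8 of 21 progenitor genes, 11 and 8 of 25 apoptosis regulators, 14 and 7 of 26 stress genes, 13 and 13 of 32 H3K9 machinery genes, 5 and 3 of 16 histone genes, 120 and 124 of 369 ZNF genes, 4 and 2 of 9 germline genes, 3 and 0 of 9 epithelial markers, 2 and 3 of 7 lymphoid markers and 1 and 2 of 4 erythroid genes. The histone median of 0.56 moved with single libraries, to 0.16 without hairpin 2 replicate 3, 0.25 without hairpin 4 replicate 2 and 0.33 without scrambled replicate 1. Against DMSO 11 histone genes were higher and 1 lower (median 0.89), and the list did not pass. For progenitor, ZNF and erythroid genes the medians (0.05, 0.01 and 0.11) and means were positive while the test pointed down, and for H3K9 machinery the median was 0.02 and the mean -0.08. The ZNF median lay below 0 with RLE in place of TMM scaling. Against DMSO apoptosis regulators (median 0.08), H3K9 machinery (-0.09) and lymphoid markers (-0.68) passed. Apart from histone genes (4 and 3) and erythroid genes (2 and 2), counts adjusted over the list alone were unchanged. In all, 13658 genes (67.8%) differed, 7077 higher and 6581 lower, of which 1482 and 425 differed at least 2-fold. SUV39H1 hairpins 2 and 4 gave 13518 and 12279 calls separately.

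The SUV39H1 hairpins differed from each other. Of 73 interferon-stimulated genes 70 were higher with hairpin 2 than with hairpin 4 and none lower, over all genes and adjusted over the list alone, with a median of 0.98 (camera, Benjamini-Hochberg adjusted p = 2.16e-141; adjusted p = 1.99e-12 with an estimated correlation). OAS2 stood at 9.12 ± 0.088 against 0.809 ± 0.096 CPM and IFI44 at 31.7 ± 0.53 against 3.62 ± 0.16 CPM. All 4 methyltransferase transcripts were lower with hairpin 2, SUV39H2 by a log2 change of -0.60 ± 0.07 and SUV39H1 by -0.18 ± 0.07. The SUV39H1 call ended without hairpin 2 replicate 1, 2 or 3 (-0.16, -0.19 and -0.19) and without hairpin 4 replicate 3 (-0.12). The asparagine synthetase gene ASNS stood at 61.3 ± 2.7 against 182 ± 0.95 CPM, and stress genes were lower in 14 of 26 and higher in 6, or 15 and 6 adjusted over the list alone (median -0.14; camera, Benjamini-Hochberg adjusted p = 8.27e-07; adjusted p = 0.00026 with an estimated correlation). Ribosome biogenesis genes were lower in 30 of 32, over all genes and adjusted over the list alone (median -0.37; camera, Benjamini-Hochberg adjusted p = 7.55e-13; adjusted p = 5.75e-05 with an estimated correlation). In all, 8645 genes differed, 4207 higher and 4438 lower with hairpin 2.

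**Figure D3:**
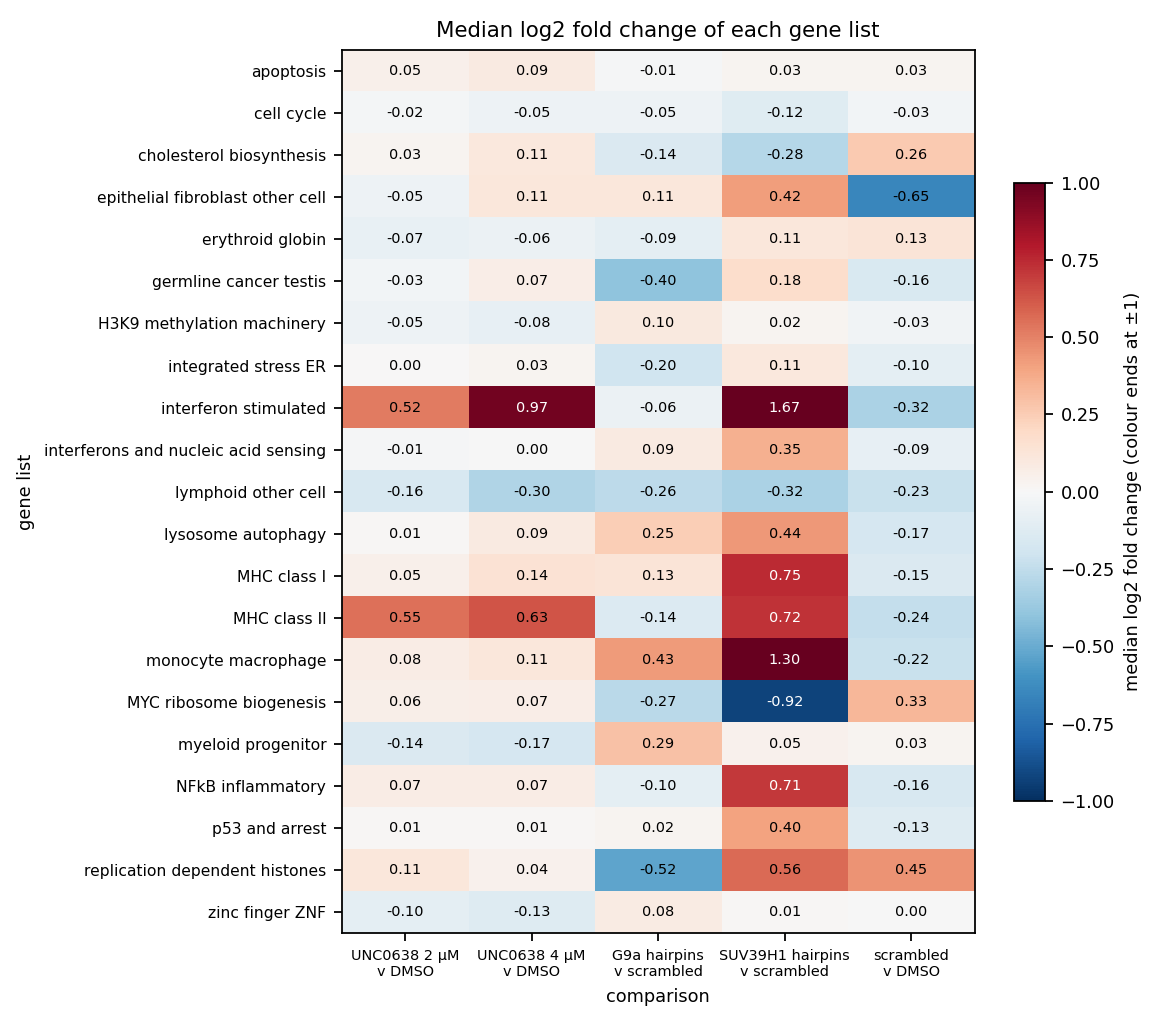
Median log2 fold change (colour and printed value) of the 21 gene lists (y axis) in 5 comparisons (x axis). The interferon-stimulated list stands at 0.52, 0.97, -0.06, 1.67 and -0.32, and ribosome biogenesis at 0.06, 0.07, -0.27, -0.92 and 0.33, from left to right.

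The knockdowns were compared directly with each other. Of 73 interferon-stimulated genes 67 were lower with the G9a than with the SUV39H1 hairpins and 1 was higher, over all genes and adjusted over the list alone, with a median of -1.60 (camera, Benjamini-Hochberg adjusted p = 8.47e-152; adjusted p = 1.43e-12 with an estimated correlation). IFI6 was lower by a log2 difference of -4.63 ± 0.06 and the transporter SLCO2B1 by -4.53 ± 0.07, while CLEC5A was 2.49 ± 0.04 higher. Ribosome biogenesis genes were higher with the G9a hairpins in all 32 members, over all genes and adjusted over the list alone (median 0.62; camera, Benjamini-Hochberg adjusted p = 1.11e-24; adjusted p = 1.06e-06 with an estimated correlation). Overall 13197 genes differed, 6624 higher and 6573 lower. Against scrambled, both knockdowns raised 3619 genes, where independent lists would share 1770, and lowered 3407, where they would share 1640. They moved 460 genes up with G9a and down with SUV39H1 hairpins (1646 if independent) and 671 the other way (1763). Fold changes correlated across genes, which are not independent replicates (Pearson r = 0.51, Spearman rho = 0.58), where unchanged groups simulated against the shared scrambled libraries gave r = 0.68. The covariance was 0.146 against 0.0254 simulated. The 3 scrambled libraries cannot be split, so part of the excess may come from the shared controls.

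The inhibitor and the G9a hairpins were compared through the difference of their responses, each against its own control. The 4 µM response exceeded the G9a hairpin response in 56 of 73 interferon-stimulated genes and was below it in 1, or 57 and 2 adjusted over the list alone, with a median difference of 0.86 (camera, Benjamini-Hochberg adjusted p = 1.5e-58; adjusted p = 2.47e-09 with an estimated correlation). IL22RA2 (4.75 ± 0.12), IFI27 (3.90 ± 0.27) and MMP1 (3.71 ± 0.14) had a more positive response to the inhibitor. ZNF117 (-3.59 ± 0.16), KCNMB1 (-3.13 ± 0.11) and CHI3L1 (-2.51 ± 0.06) had a more negative one. ZNF117 fell with the inhibitor (-2.23 ± 0.13) and rose with the hairpins (1.36 ± 0.09), while KCNMB1 (2.99 ± 0.07) and CHI3L1 (2.50 ± 0.04) rose with the hairpins and did not pass with the inhibitor. The response to the inhibitor was the more positive in 11 of 14 MHC class II genes and 25 of 32 ribosome genes (11 and 27 adjusted over the list alone), and in ZNF genes the more negative in 169 of 369 and the more positive in 33 (175 and 35 adjusted over the list alone). Each passed camera (Benjamini-Hochberg adjusted p = 4.48e-09, 2.86e-11 and 2.5e-06; adjusted p = 0.00571, 0.000142 and 0.0114 with an estimated correlation). Any gap between the scrambled and DMSO libraries enters these differences. Against DMSO the G9a hairpins gave a ribosome list median of 0.05, with 13 members higher and 7 lower, so that list's difference depended on the control. The interferon, MHC class II and ZNF medians against DMSO were -0.35, -0.36 and 0.06. In all, 9020 genes differed in response, 4528 more positive with the inhibitor and 4492 less. These comparisons share no control library, and their fold changes correlated negatively across genes, which are not independent replicates (Pearson r = -0.18, Spearman rho = -0.23). Genes raised by both numbered 444, where independent lists would share 513, and genes raised by the inhibitor and lowered by the hairpins 918, where they would share 511.

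The controls themselves differed. In scrambled against DMSO libraries, 6321 genes passed, 2993 higher and 3328 lower. The cytokine-like matrix protein SPP1 stood at 0.740 ± 0.24 against 16.7 ± 0.85 CPM and HMOX1 at 8.81 ± 0.21 against 105 ± 9.9 CPM. Interferon-stimulated genes were lower in 48 of 73 and higher in 4, or 49 and 4 adjusted over the list alone (median -0.32; camera, Benjamini-Hochberg adjusted p = 3.37e-16; adjusted p = 1.56e-07 with an estimated correlation). Ribosome genes were higher in 30 of 32, or 31 adjusted over the list alone (median 0.33; camera, Benjamini-Hochberg adjusted p = 6.38e-26; adjusted p = 1.06e-06 with an estimated correlation), and sterol genes in 15 of 22, or 16 adjusted over the list alone (median 0.26; camera, Benjamini-Hochberg adjusted p = 1.84e-10; adjusted p = 1.97e-05 with an estimated correlation). Lysosome genes were lower in 22 of 32, or 23 adjusted over the list alone (median -0.17; camera, Benjamini-Hochberg adjusted p = 7.78e-08; adjusted p = 0.0434 with an estimated correlation). Set against DMSO, the interferon list had a median of -0.35 with the G9a hairpins and 1.32 with the SUV39H1 hairpins.

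Repeats, which H3K9 methylation helps to silence, rose with both knockdowns when scaled by the gene table. Of 928 repeat names, 638 rose and 38 fell with the G9a hairpins (median 0.28) and 699 rose and 62 fell with the SUV39H1 hairpins (median 0.35). Scaled by their own TMM factors, which removes a shift shared by all repeats, 167 rose and 196 fell with the G9a hairpins (median 0.02) and 260 rose and 227 fell with the SUV39H1 hairpins (median 0.03). Repeat counts made up 5.76 ± 0.115% of gene counts in scrambled, 6.96 ± 0.0697% and 6.79 ± 0.343% with G9a hairpins 2 and 3, and 7.40 ± 0.213% and 7.79 ± 0.0485% with SUV39H1 hairpins 2 and 4. Young LINE-1 names (L1HS and L1PA) rose in 16 of 18 with the G9a hairpins (median 0.43; camera, Benjamini-Hochberg adjusted p = 8.46e-05) and in 17 with the SUV39H1 hairpins (median 0.53; camera, Benjamini-Hochberg adjusted p = 0.00682). Older LINE-1 names (L1PB and L1M) rose in 78 of 85 with each, and 1 fell with the SUV39H1 hairpins (medians 0.30 and 0.38; camera, Benjamini-Hochberg adjusted p = 8.46e-05 and 0.0162). Each of these 4 calls ended with an estimated correlation (adjusted p = 0.998). Under their own TMM factors 13 young LINE-1 names rose with each, and 1 and 2 fell (medians 0.17 and 0.21), while only 30 and 32 older names rose and 11 fell with each (medians 0.04 and 0.05). Adjusted over the list alone, 79 older LINE-1 names rose with the G9a hairpins. Among the single names that the naming rule took, the satellite SATR2 (1.06 ± 0.11) rose most with the G9a hairpins and LTR13_ fell most (-1.52 ± 0.08), while 8 names over all rose and 2 fell at least 2-fold. MamGypLTR2c (1.39 ± 0.11), the satellite HSAT4 (1.28 ± 0.09) and the retroviral HERVE-int (1.12 ± 0.05) rose with the SUV39H1 hairpins, and SST1 fell (-0.88 ± 0.05).

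The other 12 repeat lists did not pass camera, which compares a list with the remaining repeats, in either knockdown, although all their medians lay above 0 under gene scaling. With fry, which makes no such comparison, all 14 repeat lists rose in both knockdowns under gene scaling (Benjamini-Hochberg adjusted p at most 0.00929). Own TMM factors lowered the median of every list by nearly the same amount, so a sign that flips marks only a rise smaller than that amount. Alu names rose in 29 of 36 with the G9a hairpins, or 30 adjusted over the list alone (median 0.27, own TMM factors 0.02 with 4 higher and 2 lower), and in 33 with the SUV39H1 hairpins (median 0.30, flipping to -0.03 under own TMM factors with 3 higher and 14 lower). Satellites rose in 7 of 13 and fell in 1 with the G9a hairpins, or 6 and 1 adjusted over the list alone, and rose in 9 and fell in 1 with the SUV39H1 hairpins (medians 0.36 and 0.66, own TMM factors 0.10 with 2 higher and 3 lower and 0.34 with 4 higher and 1 lower). HERVK with LTR5 rose in 19 of 27 with each and fell in 1 and 3 (medians 0.30 and 0.40, own TMM factors 0.05 with 7 higher and 5 lower and 0.08 with 8 and 6), and HERVE with LTR2 rose in 3 of 5 with each and fell in 2 (medians 0.28 and 0.52, own TMM factors 0.03 with 2 higher and 2 lower and 0.19 with 3 and 2). HERVH with LTR7 rose in 14 of 20 with each and fell in 2 with the SUV39H1 hairpins (medians 0.26 and 0.35, own TMM factors -0.0022 with 3 higher and 3 lower, a flip, and 0.03 with 5 and 4). THE1, MST and MLT names rose in 67 of 90 and fell in 3 with the G9a hairpins (median 0.25, flipping to -0.01 under own TMM factors with 14 higher and 15 lower) and rose in 75 and fell in 3 with the SUV39H1 hairpins, or 76 and 3 adjusted over the list alone (median 0.36, own TMM factors 0.03 with 25 higher and 13 lower). MLT2 names rose in 29 and 27 of 38 and fell in 2 and 3 (medians 0.22 and 0.35, own TMM factors -0.04 with 4 higher and 9 lower, a flip, and 0.03 with 11 and 11). LTR12 with HERV9 rose in 3 and 5 of 8 (medians 0.14 and 0.20, own TMM factors flipped to -0.12 in each with none and 1 higher and 2 and 4 lower), and HERVW with LTR17 in 1 and 2 of 2 (0.19 and 0.25, own TMM factors flipped to -0.07 and -0.08 with none higher and 1 lower in each). MER41 and MER61 rose in 5 and 7 of 14 and fell in 3 and 4 (0.16 and 0.19, own TMM factors flipped to -0.10 and -0.13 with 1 and 3 higher and 7 lower in each), and SVA rose in 4 and 3 of 6, or 4 and 2 adjusted over the list alone (0.21 and 0.13, own TMM factors flipped to -0.05 and -0.19 with none and 2 higher and 2 and 4 lower). DNA transposons rose in 82 and 85 of 124 and fell in 4 and 12, or 81 and 4 with the G9a hairpins adjusted over the list alone (0.23 and 0.29, own TMM factors flipped to -0.03 in each with 14 and 20 higher and 42 and 44 lower).

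**Figure D4:**
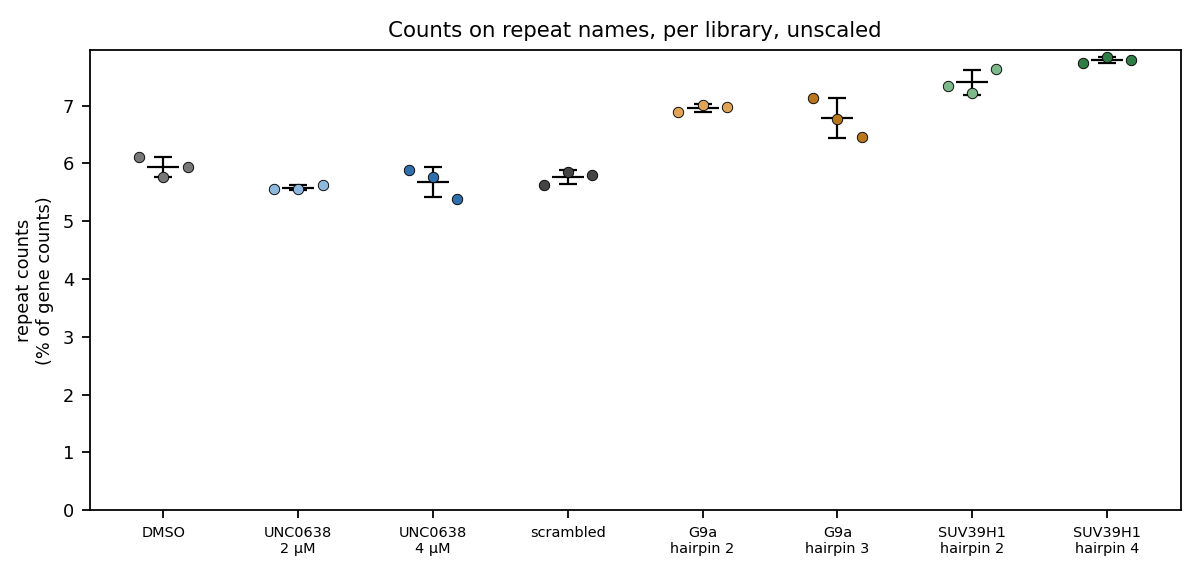
Counts on repeat names as a percentage of gene counts (y axis, unscaled) in the 24 libraries by group (x axis); points are libraries and bars mean ± SD of 3. The 12 knockdown libraries start at 6.45%, above the highest scrambled library at 5.85%.

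With UNC0638 few repeats moved and most fell. At 4 µM 69 names differed, 25 higher and 44 lower (median -0.06), and at 2 µM 45, 7 higher and 38 lower (median -0.09). Under their own TMM factors the splits were 68 higher and 27 lower at 4 µM and 25 and 8 at 2 µM, so the direction of the majority depended on the scaling. Alu names fell in 4 of 36 at 4 µM and 3 at 2 µM, or 12 and 24 adjusted over the list alone (medians -0.11 and -0.13; camera, Benjamini-Hochberg adjusted p = 0.00266 for each), and older LINE-1 names fell in 4 of 85 at 2 µM (median -0.11; camera, Benjamini-Hochberg adjusted p = 0.0237). These calls ended with an estimated correlation (adjusted p = 0.998). Under own TMM factors the calls of single Alu names ended, and the Alu medians stayed below 0 (-0.05 at 4 µM and -0.03 at 2 µM), as did that of older LINE-1 names at 2 µM (-0.02). SST1 (-0.61 ± 0.06) and LTR13_ (-0.55 ± 0.09) fell at 4 µM, and the SINE FAM (0.46 ± 0.04) and MER61A (0.44 ± 0.06) rose. No other repeat list passed camera at either dose. With fry under gene scaling, the Alu, HERVK, SVA and satellite lists fell at both doses (Benjamini-Hochberg adjusted p at most 0.0447). Older LINE-1 names at 2 µM did not pass fry (Benjamini-Hochberg adjusted p = 0.0885). The 4 µM count was 44 and 39 without 4 µM replicates 2 and 3, 32 without DMSO replicate 3 and 31 from the compared libraries alone. The 2 µM count was 13 and 25 without 2 µM replicates 1 and 2, 27 and 17 without DMSO replicates 2 and 3 and 77 by DESeq2.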

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

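The tests on scrambled libraries as the source of the shared shift, on hairpin delivery, on sense intronic genes and on other splits of the samples were chosen beforehand, and all other tests here were chosen only after the result was seen, the test on genes inside other genes after that on sense intronic genes had been read.

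Differences between groups drew attention to 8 results. The SUV39H1 hairpins differed from each other in 8645 genes and by a median of 0.98 in the interferon list, higher with hairpin 2. The knockdowns differed in 13197 genes and by a median of -1.60 in that list, G9a minus SUV39H1. The 4 µM UNC0638 response differed from the G9a hairpin response in 9020 genes and by a median of 0.86 in that list. The doses of UNC0638 differed in 371 genes, and the G9a hairpins in 2.

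Repeat names rose broadly with both knockdowns under gene scaling, and no explanation weighed here is argued against. Scaling by the gene table stays open: repeat counts as a share of gene counts lay above scrambled in every knockdown library, by 0.606 percentage points between the nearest libraries, but such a share is itself scaled by genes, and the repeats' own TMM factors (medians 0.02 and 0.03) centre the repeats. More unspliced RNA may contribute and stays open: sense intronic genes lay 0.29 above all genes in the knockdown where they rose less, but 74.6% of tested genes could be typed by name, short of the 80% needed, so that test is void. Unspliced genes lying inside spliced genes had a median of -0.073 against all genes with the SUV39H1 hairpins and 0.03 with the G9a hairpins. They lay 0.15 and 0.11 above unspliced genes lying apart. The reference thus decides the sign with the SUV39H1 hairpins, while both values were positive with the G9a hairpins. Release of young repeats from H3K9 methylation is a hypothesis that also stays open, since young LINE-1 exceeded ancient repeats by 0.15 and 0.25 with G9a and SUV39H1 hairpins, where 0.2 in both had been asked.

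The G9a hairpin groups hardly differed, with 3.83% of genes at an unadjusted p under 0.05, fewer than chance alone would give on average. A single library behind both labels is argued against: the closest pair between the groups differed by a chi-square of 2.26 per degree of freedom. That pair was nevertheless closer than all 24 within-group pairs of the series, whose lowest value was 2.30. The share of 3.83% could also arise from 1 hairpin or 1 cell population behind both labels. The mean for pairs between the groups, 6.04, lay between those for pairs within hairpin 2 (4.90) and within hairpin 3 (7.07). Separate hairpins acting through EHMT2 at equal strength could give the same picture: EHMT2 did not differ, but genes called with the G9a hairpins correlated with the UNC0638 response at r = -0.254 across genes, which are not independent, so this stays open. No library of another hairpin or a rescue was analysed here.

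Knockdown responses depended on which control they were set against. Hairpin delivery or selection that moved all hairpin groups alike, and nothing more, is argued against. The 10058 and 13658 genes called with G9a and SUV39H1 hairpins against scrambled had already shown this, so the share below adds little. Of the genes that differed between scrambled and DMSO, 32.3% lay on the scrambled side of DMSO in both knockdowns. Knockdown effects laid over such a shift would also lower this share, so delivery together with knockdown effects stays open. Interferon genes raised in scrambled could hide a rise with the G9a hairpins. A rise above the DMSO level is argued against by the list median of -0.32 in scrambled against DMSO. Culture conditions that lowered the list in all hairpin groups could mask a rise due to the scrambled hairpin, so that case stays open. A shift of the scrambled libraries alone may account for part of the pattern and stays open: set against DMSO, called genes kept 66.0% of their median change with G9a hairpins and 71.1% with SUV39H1 hairpins, but these genes were chosen by their change against scrambled, so noise in the scrambled libraries alone would also lower these shares. Libraries with another non-targeting hairpin were not analysed here, and the design does not separate the scrambled hairpin from the conditions of its cultures.

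Among 30 drawn splits of the libraries, the real one included, 1 (the real one) reached the real count in each comparison of means. That is the smallest share that 30 splits can give, so chance is less likely there but not excluded. The real and highest other counts were 10058 and 4400 genes for the G9a mean, 13658 and 973 for the SUV39H1 mean, 13197 and 4488 between the knockdowns, 9020 and 2571 for the UNC0638 against G9a response, and for repeats 676 and 433 with G9a and 761 and 5 with SUV39H1 hairpins. Comparisons of 3 with 3 libraries have 10 splits, too few for a share under 0.05. Their real and highest other counts were 4012 and 2879 for 4 µM UNC0638, 6321 and 2589 for scrambled against DMSO, 8645 and 16 between the SUV39H1 hairpins, and 69 and 23 for repeats at 4 µM. For 2 µM UNC0638 (1444), the doses (371), each G9a hairpin (8946 and 9004), each SUV39H1 hairpin (13518 and 12279), the G9a hairpins (2) and repeats at 2 µM (45), the highest other count was 0. The split with 2879 calls exchanged DMSO replicate 1 and 4 µM replicate 3, which points to a structure of these samples beyond their groups.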

How the results depend on the processing

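The DMSO libraries as control and the inhibitor arm without the libraries numbered 1 were alternatives chosen after seeing the data, and all others were planned. Of the gene counts under alternatives 179 stayed within 1.5 times the main count and 15 did not. Of results for lists other than the interferon list 1007 kept their side of the threshold, 56 newly passed, 14 no longer passed and 3 reversed. For named genes and repeats these numbers were 6814, 23, 181 and 15. A result counted as reversed when its sign, or for lists the direction of the test, changed and at least 1 of the fits passed. A value near 0 that no longer passed could thus count. Results that kept their side by passing in both fits also kept their direction, while those past the threshold in neither fit may have changed sign. With the compared libraries alone, calls numbered 1993 at 4 µM, 717 at 2 µM, 236 between doses and 1 between G9a hairpins, with fewer libraries to estimate the spread, and 31 for repeats at 4 µM. Without a filter the G9a hairpins differed in 11 genes. DESeq2 called 77 repeats at 2 µM, and the arm without libraries numbered 1 called 14; the cause was not tested. Leaving out 1 library gave 2690 to 5518 genes at 4 µM, 995 to 2197 at 2 µM (most without DMSO replicate 1), 215 to 276 between doses, 0 to 2 between G9a hairpins (771 at an unadjusted p under 0.05 in edgeR and 3 by DESeq2 over all libraries), 8600 to 9990 for the G9a mean, 12591 to 13536 for the SUV39H1 mean, 32 to 75 repeats at 4 µM and 13 to 34 at 2 µM. The interferon list median ranged from 0.91 to 0.96 at 4 µM, 0.47 to 0.53 at 2 µM, 1.65 to 1.74 with SUV39H1 and -0.13 to -0.06 with G9a hairpins. With G9a hairpins it passed with fry (-0.059) and against DMSO (-0.35), where scrambled libraries also lay lower (-0.32).

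Repeats under their own TMM factors numbered 363 with G9a hairpins, 487 with SUV39H1 hairpins, 33 at 2 µM and 95 at 4 µM, since that scaling removes a shift shared by all repeats. Against the DMSO libraries, which may also differ in hairpin delivery and selection, these log2 changes with G9a hairpins reversed: ALINE 0.19, BTG2 -0.10, CD36 0.13, HMOX1 -1.95, IL10RB -0.32, INSIG1 0.038, KDM3A -0.54, NCL 0.039, PAGE1 0.0048, STAG3 -0.0036, SUV39H2 0.024 and TAPBP -0.074, and the test directions of sterol genes (median 0.14), lysosome genes (0.043) and ribosome genes (0.049). With SUV39H1 hairpins DDIT4 (-0.21), HMOX1 (-0.35) and STAG3 (-0.026) reversed. Some of these values lay near 0, and the lysosome list with G9a hairpins did not pass against DMSO, so not all are effects in the opposite direction. The cause was not tested. Against DMSO 5913 of 10058 G9a calls and 10219 of 13658 SUV39H1 calls kept their direction and call.

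With the replicate number as a block, the calls numbered 4642 at 4 µM, 1703 at 2 µM, 10477 for the G9a mean and 13942 for the SUV39H1 mean. MHC class II genes with G9a hairpins then did not pass (median -0.14), while lysosome genes at 2 µM (0.02) and SUV39H2 with G9a hairpin 2 (-0.15) did. By the limit set, a correlation above 0.1 in all 3 pairs, the numbers paired the samples in none of 9 pairs of groups. Of 27 same-number pairs 7 correlated above 0.1 (range -0.07 to 0.23). All 3 libraries at 4 µM and 2 of 3 at 2 µM correlated best with the DMSO library of their own number, but in no other pair of groups did all 3. Pairing by number in the inhibitor arm, which the main fit does not use, therefore stays open. Genes encoding interferons held at most 80 counts over 3 libraries, and whether depth limited them was not tested. In simulated data at the real depth 38.0% of 1.2-fold changes were called at 4 µM, and depth was not varied.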

Other observations

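The overlap of the UNC0638 and SUV39H1 responses was chosen after seeing the data. Outside the interferon list, SUV39H1 hairpin 2 stood above hairpin 4 in further immune groups. MHC class II genes were higher in 13 of 14, over all genes and adjusted over the list alone (median 0.62; camera, Benjamini-Hochberg adjusted p = 2.5e-06; adjusted p = 0.0158 with an estimated correlation), and monocyte markers higher in 17 of 25 and lower in 4 (median 0.45; camera, Benjamini-Hochberg adjusted p = 2.57e-11; adjusted p = 1.14e-05 with an estimated correlation). ZNF genes were lower in 146 of 369 and higher in 32, or 152 and 33 adjusted over the list alone (median -0.13; camera, Benjamini-Hochberg adjusted p = 0.000188; adjusted p = 0.0372 with an estimated correlation). Between the knockdowns, NF-kB genes were lower with the G9a hairpins in 25 of 27 and higher in 2 (median -0.68; camera, Benjamini-Hochberg adjusted p = 1.28e-15; adjusted p = 1.21e-05 with an estimated correlation).

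Across genes, which are not independent, the 4 µM UNC0638 and SUV39H1 responses correlated at r = 0.08 (Spearman rho = -0.11) with no control library in common, although both raised the interferon list. Both raised 831 genes, where independent lists would share 721, and both lowered 475, where they would share 640. Genes raised by the inhibitor and lowered by the hairpins numbered 803 (670 if independent), and genes lowered by the inhibitor and raised by the hairpins 1056 (688 if independent).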
